A study of Mus musculus with 18 samples.

How the data were processed

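Total RNA was extracted with TRIzol from frozen whole kidney, and 10 ng per sample was amplified and made into libraries by single primer isothermal amplification, as the labels describe. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with TopHat2 2.07 to mouse build NCBIM37, counted per gene with HTSeq and normalized with DESeq. The sources do not say whether counting used strand, so values of genes that overlap a gene on the other strand are uncertain. The deposited raw table holds, in the unit count, reads per gene for 37991 gene identifiers and 5 tallies of reads assigned to no gene. The deposited normalized table holds, in the unit signal, the raw counts divided by 1 size factor per sample, which ranged from 0.218 to 1.97. The raw counts were used for every test. Symbols came from the GENCODE M21 annotation by gene identifier and were found for 32919 identifiers, and 5072 had none. That annotation belongs to a later build than NCBIM37, so no coordinates are given.

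Gene counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, low-count filter filterByExpr over the 6 groups) in 1 fit over all 18 libraries with the 6 groups as the only term. The 9 contrasts were each day against untreated and each time against the time before, and 1 further F test asked for any difference across the 6 groups. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Gene p-values are two-sided and from edgeR unless another tool is named. Levels are CPM with TMM scaling, given as mean ± SD of 3 libraries. Folds and log2 fold changes are the fitted ones with their standard error (SE). For a group without a read, a fold is given as a lower bound with a floor of 3 counts over the group.

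There were 26 gene lists with 809 entries, written before the data were examined, of which 801 were found and 8 were not. The lists cover tubular injury, proximal tubule, loop of Henle and distal tubule, collecting duct, podocyte, endothelium, matrix and myofibroblast, macrophage and monocyte, T and natural killer cell, B and plasma cell, neutrophil, cell cycle, cytokine and chemokine, complement, interferon response, antigen presentation, fatty acid oxidation, oxidative phosphorylation, folate and one-carbon metabolism, p53 targets, NRF2 targets, cholesterol synthesis, unfolded protein response, immediate early genes, red blood cell, and adrenal and adipose tissue as a sign of carry-over. Each list was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated from the data. List p-values are Benjamini-Hochberg adjusted over the 26 lists of a comparison. Camera compares a list with all other genes. Some genes stand in more than 1 list, such as Lcn2 (tubular injury and neutrophil) and Timp1 (tubular injury and matrix).

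Genes named for a comparison with untreated kidney were the 6 largest changes in each direction among genes that passed with a real symbol, a mean of at least 10 CPM in the higher group and no overlap between the groups. They were also up to 4 members of each list with the largest change, members that moved the other way, and a fixed panel of 13 genes. Between consecutive times the 3 largest in each direction and the list members were taken. Pltp was added to the panel from memory of the published study, which was not checked. The groups, tests, lists, naming rule and alternatives were set before the data were examined, apart from 3 alternatives added later, which left out day 2 replicate 2, the mitochondrial genes, or day 14 replicate 3 for the lists.

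Alternatives changed the scaling, the low-count filter, the tool (DESeq2 1.42.0 or limma-voom), a replicate-number block, the groups fitted (only those compared), or left out each library in turn. DESeq2 used its own size factors and its own filter on mean count, and fits on fewer libraries applied the low-count filter and the scaling anew, so these changed more than the choice named. Where a library was left out, its group's 2 others were fitted with a dispersion that pools all groups. No library was a copy of another of its group. The replicate numbers carried no pairing: correlations of libraries with the same number, after group means were removed, lay between -0.033 and 0.042. The tests were run on simulated counts with 50 genes changed at each of 4 sizes. The computations used R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.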

Results

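RNA from whole kidney of male Balb/c mice was sequenced in 18 libraries that fall into 6 groups of 3. The groups are untreated kidney and kidney taken 1, 2, 3, 7 and 14 days after a single intraperitoneal injection of 250 mg/kg folic acid, a dose that injures the renal tubule and is followed by scarring. The labels give no treatment for the untreated mice and there is no group with the bicarbonate vehicle alone, so vehicle and folic acid cannot be told apart. The series title names Cdh11 and Mrc1 as markers of kidney fibrosis, and the time course asks how genes change between acute injury and fibrosis. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples.

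Reads assigned to genes (M, 1e6 reads) numbered 23.1, 47.3 and 22.2 M in the untreated libraries, and 26.9, 49.9 and 54.6 M at day 1. They numbered 45.5, 8.68 and 24.6 M at day 2, and 25.2, 20.5 and 34.2 M at day 3. At day 7 they numbered 23.4, 20.7 and 24.2 M, and at day 14 they numbered 22.2, 28.6 and 22.3 M. The 37 genes of the mitochondrial genome took 59.0 to 75.6% of these reads, most of them in the ribosomal RNAs mt-Rnr2 and mt-Rnr1. The mitochondrial share was 72.3 ± 3.22% in untreated kidney (mean ± SD, n = 3, as for all values below), 65.0 ± 2.10% at day 2, 61.6 ± 3.52% at day 3 and 70.3 ± 2.83% at day 14. All other genes together held 2.83 to 17.2 M reads per library, and 17033 to 21092 genes had a read. Reads that aligned to more than 1 place, 18.4 to 28.5% of each library, were tallied apart from genes, so values of genes with near-identical copies, such as C1s1, Lyz2 and the hemoglobin genes, are uncertain. Levels are CPM (counts per M reads) after TMM scaling. PCR reads without molecular identifiers are not independent molecules, so the lower bounds given below for genes with few reads cover counting error only.

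Across the 6 groups, 3315 of 16824 genes tested (19.7%) differed at an adjusted p under 0.05. Against untreated kidney, 1792 genes had changed at day 1, 2216 at day 2, 1280 at day 3, 1298 at day 7 and 260 at day 14. These 5 comparisons share the untreated libraries, so their lists are not independent. Some fits gave more at day 1 than at day 2.

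**Figure D1:**
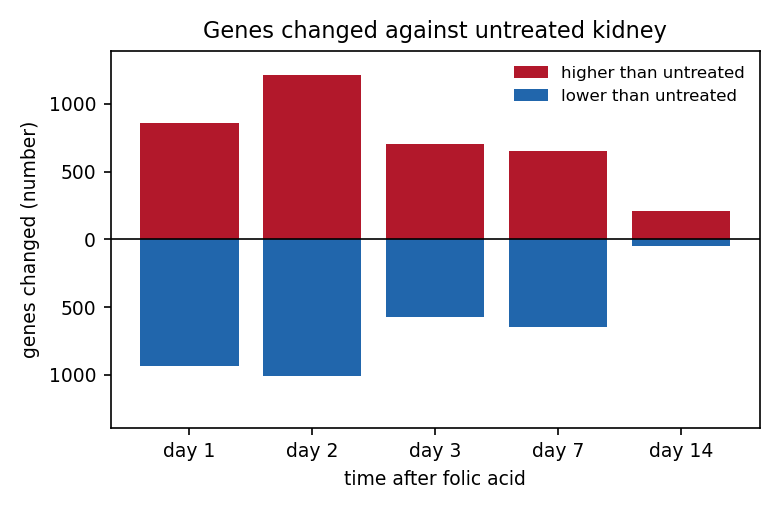
Genes higher (upward bars) and lower (downward bars) than in untreated kidney at each day after folic acid, edgeR adjusted p under 0.05, n = 3 libraries per group; the vertical axis is the number of genes. At day 14, 208 genes were higher and 52 lower, against 1210 and 1006 at day 2.

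At day 1, markers of injured tubule had risen steeply while transporters and enzymes of the healthy tubule had fallen. Havcr1 (ENSMUSG00000040405), which encodes kidney injury molecule 1, rose 142-fold, from 16.4 ± 6.52 to 2338 ± 97.1 CPM (log2 fold change 7.15, SE 0.41, adjusted p = 9.78e-09). Spp1, the secreted glycoprotein osteopontin, rose 117-fold to 13700 ± 2383 CPM, and Lcn2, an iron-carrier-binding lipocalin released by injured tubule, rose 158-fold to 107 ± 36.7 CPM. Of the 27 genes of the tubular injury list, 22 rose and 5 did not pass (23 rose adjusted over the list alone, median log2 fold change 3.75, adjusted p = 4.25e-30, and adjusted p = 0.00483 with an estimated correlation). The fibrinogen chain gene Fgb had no read in untreated kidney and was at least 263-fold higher at day 1. Without untreated replicate 2 the log2 fold change of Lcn2 was 8.63, against 7.30 with all libraries.

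Genes of the proximal tubule, the segment that reabsorbs most filtered solutes, fell as a group. Of its 54 genes, 38 fell, 1 rose and 15 did not pass (47 and 2 adjusted over the list alone, median log2 fold change -2.06, adjusted p = 1.29e-31, and adjusted p = 0.0132 with an estimated correlation). G6pc, the last enzyme of glucose release, fell 67.8-fold from 207 ± 53.3 to 3.09 ± 2.33 CPM (log2 fold change -6.08, SE 0.58, adjusted p = 2.67e-06). Gatm, the first enzyme of creatine synthesis, fell 38-fold, the amino acid transporter gene Slc7a13 fell 41.5-fold, and the sodium-phosphate cotransporter gene Slc34a1 fell 17.8-fold from 707 ± 91.2 to 39.7 ± 8.08 CPM. The sodium-sulfate cotransporter gene Slc13a1 went the other way and rose 3.86-fold to 566 ± 75.6 CPM. In the loop of Henle and distal tubule, 16 of 23 genes fell and 7 did not pass (19 fell adjusted over the list alone, median log2 fold change -2.02, adjusted p = 1.02e-17, and adjusted p = 0.00483 with an estimated correlation). Egf, a growth factor made in these segments, fell 84.1-fold from 306 ± 23.3 to 3.66 ± 1.25 CPM. Slc12a1, the sodium-potassium-chloride cotransporter that loop diuretics block, fell 26.4-fold, and Umod, which encodes uromodulin, fell 4.01-fold to 217 ± 85.8 CPM. In the collecting duct list 8 of 23 genes fell (8 adjusted over the list alone, median log2 fold change -1.10, adjusted p = 2.22e-08, and adjusted p = 0.0185 with an estimated correlation). Nccrp1 had no read at day 1 and was at least 393-fold lower. The log2 fold change of G6pc was -6.79 without day 1 replicate 1.

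Enzymes of fatty acid oxidation and nuclear-coded subunits of the respiratory chain also fell at day 1. Of 40 fatty acid oxidation genes 14 fell (21 adjusted over the list alone, median log2 fold change -0.74, adjusted p = 9.23e-09, and adjusted p = 0.0185 with an estimated correlation), including the medium-chain dehydrogenase gene Acadm, which fell 4.0-fold from 193 ± 5.85 to 48.2 ± 6.12 CPM. Of 46 oxidative phosphorylation genes 17 fell (31 adjusted over the list alone, median log2 fold change -0.88, adjusted p = 8.97e-14, and adjusted p = 0.0369 with an estimated correlation), including the complex II gene Sdhb (3.0-fold) and the ATP synthase gene Atp5c1 (2.62-fold). The list of folate and one-carbon metabolism was mixed, with 12 of 35 genes lower and 3 higher (16 and 4 adjusted over the list alone, median log2 fold change -0.58, adjusted p = 0.00139, and adjusted p = 0.112 with an estimated correlation). Ftcd, which breaks down histidine with folate, fell 10.2-fold, while Mthfd2, the mitochondrial folate enzyme of dividing cells, rose 19.6-fold from 0.119 ± 0.133 CPM. On the log2 scale Mthfd2 was 4.29 higher, and 5.74 without untreated replicate 1 and 3.65 without untreated replicate 2.

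Chemokines, early response genes and the first cell cycle genes rose at day 1. Of 35 cytokine and chemokine genes 11 rose and 2 fell (15 and 2 adjusted over the list alone, median log2 fold change 1.21, adjusted p = 2.65e-07, and adjusted p = 0.0313 with an estimated correlation). The neutrophil attractant gene Cxcl1 rose 119-fold to 20.3 ± 7.57 CPM, and Cxcl12, which retains leukocytes and progenitor cells, fell 10.4-fold. Of 24 immediate early genes 11 rose (14 adjusted over the list alone, median log2 fold change 1.79, adjusted p = 2.39e-08, and adjusted p = 0.0185 with an estimated correlation), among them Ccn1, a matrix protein gene induced by stretch and growth factors, at 17.6-fold. Of 49 cell cycle genes 11 rose (15 adjusted over the list alone, median log2 fold change 1.55, adjusted p = 8.97e-09, and adjusted p = 0.0098 with an estimated correlation), among them the replication helicase gene Mcm6 (14-fold) and the ribonucleotide reductase gene Rrm2 (9.72-fold). Complement genes were mixed: C3, the central complement protein, rose 84.8-fold to 311 ± 60.1 CPM and Clu, which encodes clusterin, rose 15.5-fold, while C8a fell 11.8-fold. The complement list of 25 had 4 genes higher and 2 lower (5 and 4 adjusted over the list alone), with a median of -0.05, a mean of 0.32 and adjusted p = 0.309. Cxcl1 had a log2 fold change of 6.90, and 7.81 without untreated replicate 2.

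Of 53 matrix and myofibroblast genes 10 rose and 2 fell at day 1 (13 and 6 adjusted over the list alone, median log2 fold change 0.56, adjusted p = 0.0090, and adjusted p = 0.318 with an estimated correlation). The collagen genes Col1a1 and Col3a1 rose 9.04-fold and 3.43-fold, and Tnc, the wound matrix protein tenascin C, rose 14.2-fold. Of 34 macrophage and monocyte genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, median log2 fold change 0.40, adjusted p = 0.0323, and adjusted p = 0.34 with an estimated correlation). The endotoxin co-receptor gene Cd14 rose 47.6-fold to 44.6 ± 9.22 CPM, while Csf1r, the receptor on which macrophages depend, fell 4.02-fold. Of 24 endothelial genes 5 fell (5 adjusted over the list alone, median log2 fold change -0.57, adjusted p = 0.000468, and adjusted p = 0.0185 with an estimated correlation), including Kdr, the main receptor for vascular endothelial growth factor, at 4.33-fold. In the podocyte list 5 of 20 genes fell, including Magi2 (4.93-fold), with 6 adjusted over the list alone (median log2 fold change -0.23, adjusted p = 0.0262, and adjusted p = 0.112 with an estimated correlation). For Cd14 the log2 fold change was 5.57, and 6.404 without untreated replicate 2.

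In total 857 genes rose and 935 fell at day 1, and 4029 had an unadjusted p under 0.05. Day 1 and untreated values did not overlap for 1739 of the 1792 genes and for 31.1% of all genes tested, against a chance share of 10%. With library totals alone, which moved log2 fold changes by a median of 0.14, 885 genes rose and 672 fell. The count was 1190 without untreated replicate 1, 1190 without untreated replicate 2 and 1164 without day 1 replicate 2 (627 higher and 537 lower), and without day 1 replicate 3 713 genes were higher and 666 lower. Of 108 named genes that passed, 76 passed in each of the 6 fits that left out 1 library and 32 did not. The 76 include all the genes given above as risen or fallen, so those do not represent the named calls as a whole.

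At day 2, cell division genes rose. Of 49 cell cycle genes 34 rose (39 adjusted over the list alone, median log2 fold change 3.34, adjusted p = 3.56e-27, and adjusted p = 0.00013 with an estimated correlation). Mki67, the proliferation marker Ki-67, rose 19.1-fold from 4.03 ± 2.3 to 78.3 ± 25.7 CPM (log2 fold change 4.26, SE 0.44, adjusted p = 6.94e-06). The mitotic cyclin gene Ccnb2 rose 59.1-fold and Foxm1, a transcription factor that drives entry into mitosis, rose 53-fold to 30.1 ± 23.4 CPM. Cenpe, a motor protein of the kinetochore, had the largest rise of the list, 459-fold, but its CPM was 2330 in day 2 replicate 2 and 16.9 and 61.3 in the other 2 libraries. Without day 2 replicate 2, the library with the fewest reads, 28 cell cycle genes rose with a median log2 fold change of 2.87, and Cenpe was at 4.06 against 8.84 with all libraries and 9.62 without untreated replicate 2. Ccnb2 was at 5.89 with all libraries and at 5.04, 6.84 and 5.06 without untreated replicate 2, untreated replicate 3 and day 2 replicate 3, and Foxm1 was at 5.73, and at 6.54 and 4.99 without untreated replicate 1 and day 2 replicate 1.

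Injury markers were high at day 2 and tubule genes were low. Havcr1 was 54.1-fold higher at 890.3 ± 207 CPM, Lcn2 501-fold higher at 340.5 ± 308 CPM and Spp1 175-fold higher at 20410 ± 8237 CPM. Of 27 tubular injury genes 22 were higher (24 adjusted over the list alone, median log2 fold change 3.79, adjusted p = 3.26e-29, and adjusted p = 0.0035 with an estimated correlation). Of 54 proximal tubule genes 36 fell and 3 rose (38 and 3 adjusted over the list alone, median log2 fold change -1.66, adjusted p = 1.66e-21, and adjusted p = 0.0305 with an estimated correlation). The brush border protease gene Mep1b fell 361-fold from 38 ± 1.25 to 0.0672 ± 0.0852 CPM, the solvent-oxidising enzyme gene Cyp2e1 fell 25.1-fold and Slc34a1 fell 8.64-fold. Slc22a7, an organic anion transporter gene, had no read at day 2 and was at least 250-fold lower. Of 23 loop and distal genes 16 fell and 1 rose (16 and 1 adjusted over the list alone, median log2 fold change -1.92, adjusted p = 7.84e-12, and adjusted p = 0.00711 with an estimated correlation). Egf fell 149-fold to 1.91 ± 0.991 CPM, the calcium buffer gene Calb1 fell 8.14-fold and Umod fell 5.85-fold. Trpv5, a calcium channel gene of the distal tubule, rose 11.3-fold with values of 76.7 ± 98.5 CPM, and without day 2 replicate 2 its log2 fold change was 1.55 (adjusted p = 0.103). In the collecting duct list 7 of 23 genes fell (9 adjusted over the list alone, median log2 fold change -1.01, adjusted p = 4.46e-05, and adjusted p = 0.0554 with an estimated correlation), including the water channel gene Aqp4 at 6.2-fold. Lcn2 had a log2 fold change of 8.97, with 7.94 without day 2 replicate 2, where it was at 680.4 CPM against 259.5 and 81.68 in the other 2 libraries, and 10.28 without untreated replicate 2. Mep1b was at -8.50, and -10.08 without day 2 replicate 1.

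Vessel and podocyte genes fell at day 2. Of 24 endothelial genes 9 fell (13 adjusted over the list alone, median log2 fold change -1.65, adjusted p = 6.85e-09, and adjusted p = 0.00201 with an estimated correlation). Kdr fell 9.57-fold from 21.1 ± 7.74 to 2.11 ± 0.966 CPM and the endothelial surface protein gene Emcn fell 6.84-fold to 4.79 ± 0.533 CPM. Of 20 podocyte genes 6 fell (6 adjusted over the list alone, median log2 fold change -0.41, adjusted p = 0.00131, and adjusted p = 0.0319 with an estimated correlation), including Vegfa, the growth factor that maintains capillaries (3.08-fold). Of 40 fatty acid oxidation genes 12 fell and 2 rose (13 and 2 adjusted over the list alone, median log2 fold change -0.58, adjusted p = 0.00011, and adjusted p = 0.0895 with an estimated correlation). Scp2, a peroxisomal thiolase and lipid carrier, fell 3.93-fold. Of 46 oxidative phosphorylation genes 22 fell (31 adjusted over the list alone, median log2 fold change -0.91, adjusted p = 8.23e-13, and adjusted p = 0.0515 with an estimated correlation), including Sdha, the catalytic subunit of complex II, at 3.14-fold. Of 35 folate and one-carbon genes 8 fell and 3 rose (8 and 4 adjusted over the list alone, median log2 fold change -0.39, adjusted p = 0.0188, and adjusted p = 0.216 with an estimated correlation), with Shmt2, the mitochondrial serine hydroxymethyltransferase, down 6.47-fold.

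Inflammatory and matrix genes moved in both directions at day 2. Of 35 cytokine and chemokine genes 13 rose and 2 fell (17 and 2 adjusted over the list alone, median log2 fold change 1.73, adjusted p = 4.07e-06, and adjusted p = 0.0515 with an estimated correlation). Lif, a cytokine of the interleukin 6 family, rose by 7.23 on the log2 scale to 17.2 ± 19 CPM. C3 rose 185-fold to 678 ± 282 CPM and Clu 32.1-fold, while C8a fell 118-fold and the inhibitor gene Cd55 fell 5.12-fold. Of 34 macrophage genes 7 rose and 2 fell (8 and 3 adjusted over the list alone, median log2 fold change 0.59, adjusted p = 0.0188, and adjusted p = 0.268 with an estimated correlation), with Cd14 up 20.8-fold and the integrin gene Itgam, also known as CD11b, up 11-fold. Of 53 matrix genes 13 rose and 6 fell (14 and 9 adjusted over the list alone, median log2 fold change 0.34, adjusted p = 0.0569, and adjusted p = 0.43 with an estimated correlation). Fn1, which encodes fibronectin, rose 7.71-fold from 8.68 ± 1.57 to 67.1 ± 30.9 CPM and Col1a1 rose 10.9-fold, while Dcn, the proteoglycan decorin of resident fibroblasts, fell 7.35-fold. Of 24 immediate early genes 10 rose (14 adjusted over the list alone, median log2 fold change 1.74, adjusted p = 4.45e-08, and adjusted p = 0.0287 with an estimated correlation), including Ier3 at 15.9-fold. Lif was at 6.33, 12.03 and 5.72 on the log2 scale without untreated replicate 2, untreated replicate 3 and day 2 replicate 1. Ier3 moved from 3.99 to 3.06 without day 2 replicate 2, Dcn from -2.88 to -3.54 without day 2 replicate 3 and Cd14 from 4.38 to 5.196 without untreated replicate 2.

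In total 1210 genes rose and 1006 fell at day 2, and 4529 had an unadjusted p under 0.05. Day 2 and untreated values did not overlap for 1996 of the 2216 genes and for 28.0% of all genes tested, against a chance share of 10%. With library totals in place of TMM, which moved log2 fold changes by a median of 0.25, 1450 genes rose and 651 fell. The count was 1453, 1465 and 1464 without untreated replicate 1, 2 and 3, with more falls than rises in each (674 higher and 779 lower, 713 and 752, and 678 and 786), and 1572 without day 2 replicate 2. Of 122 named genes that passed, 77 passed in each of the 6 fits that left out 1 library, among them all given above as risen or fallen apart from Trpv5.

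At day 3, macrophage, antigen presentation, complement and matrix genes rose while tubule genes were low. C3 rose 280.2-fold from 3.65 ± 0.528 to 1026 ± 226 CPM (log2 fold change 8.13, SE 0.66, adjusted p = 5.47e-07). The monocyte attractant gene Ccl2 rose 148-fold to 13 ± 7.63 CPM, and Vcam1, an adhesion molecule for leukocytes also made by injured tubule, rose 125-fold to 198 ± 105 CPM. Of 34 macrophage and monocyte genes 12 rose (21 rose and 2 fell adjusted over the list alone, median log2 fold change 1.87, adjusted p = 3.85e-11, and adjusted p = 0.00987 with an estimated correlation), with Itgam up 33.3-fold and Cd14 up 45.9-fold. Of 22 antigen presentation genes 10 rose (15 adjusted over the list alone, median log2 fold change 1.45, adjusted p = 2.71e-10, and adjusted p = 0.00908 with an estimated correlation). The class II genes H2-Ab1 and H2-DMa rose 8.02-fold and 16.6-fold. Of 35 cytokine and chemokine genes 15 rose (21 rose and 2 fell adjusted over the list alone, median log2 fold change 2.98, adjusted p = 4.79e-14, and adjusted p = 0.0078 with an estimated correlation). Cxcl1 rose 174-fold to 29.6 ± 14 CPM, and Ccl20 had no untreated read and was at least 87.8-fold higher. Leaving out untreated replicate 2 moved the log2 fold change of Cxcl1 from 7.44 to 8.34 and that of Cd14 from 5.52 to 6.34.

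Complement, interferon and matrix lists rose at day 3. Of 25 complement genes 7 rose and 1 fell (11 and 3 adjusted over the list alone, median log2 fold change 1.39, adjusted p = 4.8e-05, and adjusted p = 0.0168 with an estimated correlation), with the serine protease gene C1s1 up 11.1-fold. Of 32 interferon response genes 7 rose (11 adjusted over the list alone, median log2 fold change 1.37, adjusted p = 1.22e-06, and adjusted p = 0.0127 with an estimated correlation). Of 53 matrix genes 17 rose (24 rose and 1 fell adjusted over the list alone, median log2 fold change 1.10, adjusted p = 2.62e-10, and adjusted p = 0.0168 with an estimated correlation). Col3a1 rose 7.15-fold from 6.62 ± 0.904 to 47.2 ± 7.47 CPM, Col1a1 rose 33.3-fold to 89.8 ± 81.7 CPM and Fn1 rose 8.46-fold. Of 49 cell cycle genes 19 rose (32 adjusted over the list alone, median log2 fold change 2.24, adjusted p = 9.32e-19, and adjusted p = 0.000883 with an estimated correlation), with Mki67 at 10.9-fold and Rrm2 at 26.2-fold. Of 24 immediate early genes 10 rose (16 adjusted over the list alone, median log2 fold change 1.71, adjusted p = 3.25e-09, and adjusted p = 0.0127 with an estimated correlation), including the transcription factor gene Klf6 at 11.1-fold. Col1a1 was at 184.1 CPM in day 3 replicate 2 and at 46.37 and 39.04 in the others, and its log2 fold change was 3.99 without that library, against 5.06. Rrm2 moved from 4.71 to 4.004 without day 3 replicate 3.

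Injury markers were high and the tubule lists low at day 3. Of 27 tubular injury genes 20 were higher (23 adjusted over the list alone, median log2 fold change 3.12, adjusted p = 2.48e-26, and adjusted p = 0.00535 with an estimated correlation), with Havcr1 at 26.8-fold and Lcn2 at 130.4-fold. Of 54 proximal tubule genes 33 were lower and 2 higher (41 and 4 adjusted over the list alone, median log2 fold change -1.39, adjusted p = 4.07e-21, and adjusted p = 0.0168 with an estimated correlation). Gatm was 11.4-fold lower and Slc34a1 2.96-fold lower, while Slc13a1 was 3.74-fold higher. Of 23 loop and distal genes 11 were lower (14 lower and 1 higher adjusted over the list alone, median log2 fold change -1.13, adjusted p = 3.05e-10, and adjusted p = 0.00987 with an estimated correlation), including Egf (12.6-fold) and Calb1 (5.26-fold). The vitamin D-dependent calcium binder gene S100g fell 13.4-fold from 161 ± 41.3 to 12 ± 6.89 CPM, and Dnase1, a secreted nuclease gene, fell 26.7-fold to 13.2 ± 3.83 CPM. Of 23 collecting duct genes 3 were lower (4 adjusted over the list alone, median log2 fold change -0.55, adjusted p = 0.000187, and adjusted p = 0.0636 with an estimated correlation), and with library totals alone the median was 0.055. Of 24 endothelial genes 7 fell (9 adjusted over the list alone, median log2 fold change -0.97, adjusted p = 2.15e-07, and adjusted p = 0.00535 with an estimated correlation), with Kdr down 6.56-fold. Lcn2 had a log2 fold change of 7.03, with 8.35 without untreated replicate 2 and 6.45 without day 3 replicate 1. Leaving out day 3 replicate 3 moved Egf from -3.65 to -4.25 and S100g from -3.74 to -4.33.

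Metabolic lists were also low at day 3. Of 40 fatty acid oxidation genes 14 fell and 2 rose (19 and 3 adjusted over the list alone, median log2 fold change -0.69, adjusted p = 1.83e-06, and adjusted p = 0.0314 with an estimated correlation), with Acadm down 3.87-fold and the electron carrier gene Etfa down 3.72-fold. Of 46 oxidative phosphorylation genes 20 fell (28 adjusted over the list alone, median log2 fold change -0.93, adjusted p = 4.8e-17, and adjusted p = 0.0168 with an estimated correlation), in the group with the lowest mitochondrial share of reads. Of 35 folate and one-carbon genes 5 fell and 2 rose (11 and 6 adjusted over the list alone, median log2 fold change -0.57, adjusted p = 0.00568, and adjusted p = 0.129 with an estimated correlation), and with library totals alone the median was 0.027. Of 20 podocyte genes 3 fell, including Vegfa at 1.94-fold (4 adjusted over the list alone, median log2 fold change -0.19, adjusted p = 0.048, and adjusted p = 0.124 with an estimated correlation), and with library totals alone the median was 0.392.

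In total 703 genes rose and 577 fell at day 3, and 3755 had an unadjusted p under 0.05. Day 3 and untreated values did not overlap for 1231 of the 1280 genes and for 28.4% of all genes tested, against a chance share of 10%. With library totals alone, which moved the median of all genes by 0.58 log2, 2042 genes rose and 196 fell. The submitters' size factors gave 675 and 620, near the TMM counts. The count was 671, 721 and 789 without untreated replicate 1, 2 and 3, with more falls than rises in the first (328 higher and 343 lower) and last (380 and 409), 743 without day 3 replicate 1 and 614 without day 3 replicate 2. Of 102 named genes that passed, 58 passed in each of the 6 fits that left out 1 library, among them all given above as risen or fallen.

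At day 7, macrophage and matrix genes were high, and the proximal tubule list was low while loop and distal genes were near their untreated level. Itgam rose 68.1-fold from 0.355 ± 0.134 to 23.4 ± 6.68 CPM (log2 fold change 6.09, SE 0.68, adjusted p = 3.85e-05). Of 34 macrophage and monocyte genes 23 rose (27 adjusted over the list alone, median log2 fold change 3.17, adjusted p = 2.93e-21, and adjusted p = 0.00503 with an estimated correlation). Cd44, the hyaluronan receptor of activated cells, rose 75.2-fold to 47.3 ± 5.72 CPM and Ccl2 rose 215-fold to 18.8 ± 5.8 CPM. Of 53 matrix genes 26 rose and 1 fell (33 and 1 adjusted over the list alone, median log2 fold change 1.57, adjusted p = 3.96e-19, and adjusted p = 0.00513 with an estimated correlation). Col3a1 rose 11.2-fold from 6.62 ± 0.904 to 73.6 ± 28.8 CPM, Fn1 10.9-fold and Col12a1 18.8-fold. Timp3, a metalloproteinase inhibitor gene abundant in healthy kidney, fell 2.92-fold from 784 ± 78.4 to 268 ± 23.9 CPM.

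Immune lists were high at day 7. Of 25 complement genes 15 rose (17 rose and 2 fell adjusted over the list alone, median log2 fold change 2.57, adjusted p = 3.59e-09, and adjusted p = 0.00509 with an estimated correlation), with C3 up 174-fold to 637 ± 24.1 CPM and the properdin gene Cfp up 13.8-fold. Of 22 antigen presentation genes 10 rose (12 adjusted over the list alone, median log2 fold change 1.52, adjusted p = 1.83e-12, and adjusted p = 0.00509 with an estimated correlation), with the invariant chain gene Cd74 up 8.17-fold to 394 ± 161 CPM. Of 35 cytokine and chemokine genes 14 rose (25 rose and 1 fell adjusted over the list alone, median log2 fold change 3.37, adjusted p = 4.01e-16, and adjusted p = 0.00509 with an estimated correlation). Of 32 interferon response genes 4 rose (6 adjusted over the list alone, median log2 fold change 1.09, adjusted p = 9.65e-06, and adjusted p = 0.019 with an estimated correlation). Of 49 cell cycle genes 7 rose (12 adjusted over the list alone, median log2 fold change 1.07, adjusted p = 1.5e-06, and adjusted p = 0.0119 with an estimated correlation), with Mki67 at 3.28-fold. Of 24 immediate early genes 11 rose (16 adjusted over the list alone, median log2 fold change 1.88, adjusted p = 3.31e-10, and adjusted p = 0.0116 with an estimated correlation), with Klf6 at 7.12-fold. Leaving out untreated replicate 2 moved the log2 fold change of Cfp from 3.78 to 5.19.

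The tubule segments differed at day 7. Of 54 proximal tubule genes 39 were lower and 2 higher (44 and 3 adjusted over the list alone, median log2 fold change -1.63, adjusted p = 1.51e-26, and adjusted p = 0.0119 with an estimated correlation). Kap, the androgen-regulated kidney protein gene, fell 9.96-fold from 3412 ± 138 to 342 ± 236 CPM (log2 fold change -3.32, SE 0.53, adjusted p = 0.000858), Slc7a13 fell 9.93-fold and Slc34a1 fell 3.35-fold. Of 23 loop and distal genes 2 were lower, Egf (4.93-fold) and the tight junction gene Cldn10 (3.51-fold), with 2 adjusted over the list alone (median log2 fold change -0.31, adjusted p = 0.0205, and adjusted p = 0.21 with an estimated correlation). With library totals alone the loop and distal median was 0.356. Umod was at 688 ± 45.7 CPM against 869 ± 143 in untreated kidney (log2 fold change -0.34, adjusted p = 0.565), and 0.343 with library totals alone. Of 27 tubular injury genes 17 were higher and 1 lower (18 and 2 adjusted over the list alone, median log2 fold change 2.61, adjusted p = 3.96e-19, and adjusted p = 0.00847 with an estimated correlation), with Havcr1 at 10.1-fold and 166 ± 34.1 CPM. Of 24 endothelial genes 1 fell, Kdr at 3.28-fold (1 adjusted over the list alone, median log2 fold change -0.45, adjusted p = 0.0156, and adjusted p = 0.0606 with an estimated correlation), and with library totals alone the median was 0.204. The call for Kdr was lost without untreated replicate 2 (log2 fold change -1.41, adjusted p = 0.0849) or day 7 replicate 1 (-1.46, adjusted p = 0.084). Kap was at -3.97 on the log2 scale without day 7 replicate 2.

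Metabolic lists were low at day 7. Of 40 fatty acid oxidation genes 17 fell and 1 rose (23 and 1 adjusted over the list alone, median log2 fold change -0.81, adjusted p = 2.23e-12, and adjusted p = 0.00832 with an estimated correlation), with Acadm down 4.78-fold from 193 ± 5.85 to 40.2 ± 10.1 CPM. Of 46 oxidative phosphorylation genes 17 fell (31 adjusted over the list alone, median log2 fold change -0.88, adjusted p = 5.33e-17, and adjusted p = 0.019 with an estimated correlation), with the ATP synthase gene Atp5b down 2.53-fold and the mitochondrial share of reads at 64.5 ± 1.59%. Of 35 folate and one-carbon genes 9 fell and 1 rose (13 and 3 adjusted over the list alone, median log2 fold change -0.54, adjusted p = 6.23e-05, and adjusted p = 0.0422 with an estimated correlation). Folr1, the folate receptor of the proximal tubule, fell 4.41-fold from 99.7 ± 7.27 to 22.6 ± 4.97 CPM, and with library totals alone the median of this list was 0.125.

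In total 651 genes rose and 647 fell at day 7, and 3663 had an unadjusted p under 0.05. Day 7 and untreated values did not overlap for 1253 of the 1298 genes and for 28.5% of all genes tested, against a chance share of 10%. With library totals alone, which moved log2 fold changes by a median of 0.67, 2390 genes rose and 175 fell. The count was 721 and 743 without untreated replicate 1 (312 higher and 409 lower) and 2 (335 and 408), 607 without day 7 replicate 1 and 829 without day 7 replicate 2. Of 94 named genes that passed, 52 passed in each of the 6 fits that left out 1 library, among them all given above as risen or fallen apart from Kdr.

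At day 14, most genes of the tubule segment lists did not pass an adjusted p under 0.05 against untreated kidney at this depth. Macrophage, antigen presentation and matrix genes were high. Col3a1 was 13.5-fold higher, from 6.62 ± 0.904 to 89.4 ± 43.3 CPM (log2 fold change 3.76, SE 0.43, adjusted p = 0.000149). Of 53 matrix genes 18 were higher and 1 lower (33 and 2 adjusted over the list alone, median log2 fold change 1.58, adjusted p = 5.14e-24, and adjusted p = 0.00301 with an estimated correlation), including Fn1 (10.4-fold), Col1a1 (19.1-fold, to 51.3 ± 39 CPM) and Col12a1 (19.4-fold). Of 34 macrophage and monocyte genes 13 were higher (28 adjusted over the list alone, median log2 fold change 2.70, adjusted p = 1.34e-23, and adjusted p = 0.00301 with an estimated correlation). The lysozyme gene Lyz2 rose 25.7-fold to 136 ± 45.9 CPM, Itgam 37.3-fold, and Ccr2, the monocyte receptor for Ccl2, 11.5-fold. Of 22 antigen presentation genes 5 were higher (13 adjusted over the list alone, median log2 fold change 1.40, adjusted p = 5.24e-15, and adjusted p = 0.00301 with an estimated correlation), including H2-Ab1 (10.7-fold) and Cd74 (6.24-fold). Of 25 complement genes 10 were higher (14 higher and 1 lower adjusted over the list alone, median log2 fold change 1.98, adjusted p = 4.11e-09, and adjusted p = 0.00342 with an estimated correlation), including C3 at 43.8-fold and the receptor gene C3ar1 at 21.4-fold. Of 35 cytokine and chemokine genes 8 were higher (20 adjusted over the list alone, median log2 fold change 2.36, adjusted p = 4.12e-16, and adjusted p = 0.00342 with an estimated correlation), including Ccl2 (79.9-fold) and Il1rn, which encodes an antagonist of the interleukin 1 receptor (33.6-fold). Day 14 replicate 3 stood apart from the other 2, with a score on the second principal component of -56.2 against -9.8 and 7.2, where day 7 libraries were at -63.0, -51.0 and -37.7. Without it 11 matrix genes (median 1.28), 8 macrophage genes (2.06), 5 antigen presentation genes (1.40), 6 complement genes (1.67) and 3 cytokine and chemokine genes (2.02) were higher, with adjusted p = 0.000846, 0.000229, 0.00294, 0.00294 and 0.00294 with an estimated correlation. The log2 fold changes without it were 3.43 for Col1a1 (from 4.25), 3.39 for Col12a1 (from 4.28), 4.46 for Itgam (from 5.22), 4.198 for C3 (from 5.45) and 3.82 for C3ar1 (from 4.42). Il1rn moved from 5.07 to 6.02 without untreated replicate 3.

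Some injury genes were high and a few tubule genes low at day 14. Of 27 tubular injury genes 11 were higher and 1 lower (16 and 3 adjusted over the list alone, median log2 fold change 1.54, adjusted p = 1.02e-12, and adjusted p = 0.031 with an estimated correlation). Cd44 was 40.1-fold higher, Vcam1 36.9-fold and Lcn2 42.6-fold at 28.9 ± 31.3 CPM, while Itgb6, an integrin subunit gene of epithelium, fell 3.14-fold from 144 ± 9.65 to 46 ± 1.22 CPM. Havcr1 was at 33.3 ± 8.8 CPM against 16.4 ± 6.52 untreated (log2 fold change 1.01, SE 0.32, adjusted p = 0.115). Of 54 proximal tubule genes 2 were lower (12 lower and 1 higher adjusted over the list alone, median log2 fold change -0.74, adjusted p = 4.14e-13, and adjusted p = 0.0713 with an estimated correlation). Slc34a1 was at 418 ± 119.6 CPM against 707 ± 91.2 (adjusted p = 0.162) and Umod at 928 ± 240.0 against 869 ± 143 CPM (adjusted p = 0.927). Nt5e, the ectoenzyme CD73 that makes adenosine, fell 3.81-fold from 86.7 ± 8.54 to 22.8 ± 7.64 CPM, the dopamine-forming enzyme gene Ddc fell 6.38-fold, the lactate transporter gene Slc16a1 fell 6.64-fold and Folr1 fell 2.79-fold. Lcn2 was at 64.97 CPM in day 14 replicate 3 and at 12.79 and 9.002 in the others, and its log2 fold change of 5.41 was 4.0 without that library and 6.74 without untreated replicate 2. Without day 14 replicate 3, 9 tubular injury genes were higher and 1 lower (median 1.34, adjusted p = 0.0308 with an estimated correlation). Neither of the 2 lower proximal tubule genes passed then, with a list median of -0.49 (adjusted p = 4.18e-07, and adjusted p = 0.086 with an estimated correlation), and the proximal minus distal median log2 CPM was 1.33 in that library against 2.58 and 2.47 in the others.

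In the fatty acid oxidation and oxidative phosphorylation lists no gene passed at day 14 by edgeR. For fatty acid oxidation the edgeR count was 0 of 40 (1 higher and 1 lower adjusted over the list alone), with 11 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom (median log2 fold change -0.38, adjusted p = 0.000193, and adjusted p = 0.0949 with an estimated correlation). For oxidative phosphorylation it was 0 of 46, also adjusted over the list alone, with 13 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom (median log2 fold change -0.48, adjusted p = 1.23e-08, and adjusted p = 0.0965 with an estimated correlation). In total 208 genes rose and 52 fell at day 14, and 2629 had an unadjusted p under 0.05. Day 14 and untreated values did not overlap for 254 of the 260 genes and for 21.9% of all genes tested, against a chance share of 10%. With library totals alone, which moved log2 fold changes by a median of 0.32, 417 genes rose and 18 fell. The count was 114, 106 and 158 without untreated replicate 1, 2 and 3 and 112 without day 14 replicate 3. Of 46 named genes that passed, 26 passed in each of the 6 fits that left out 1 library, among them all given above as risen, higher or fallen.

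**Figure D2:**
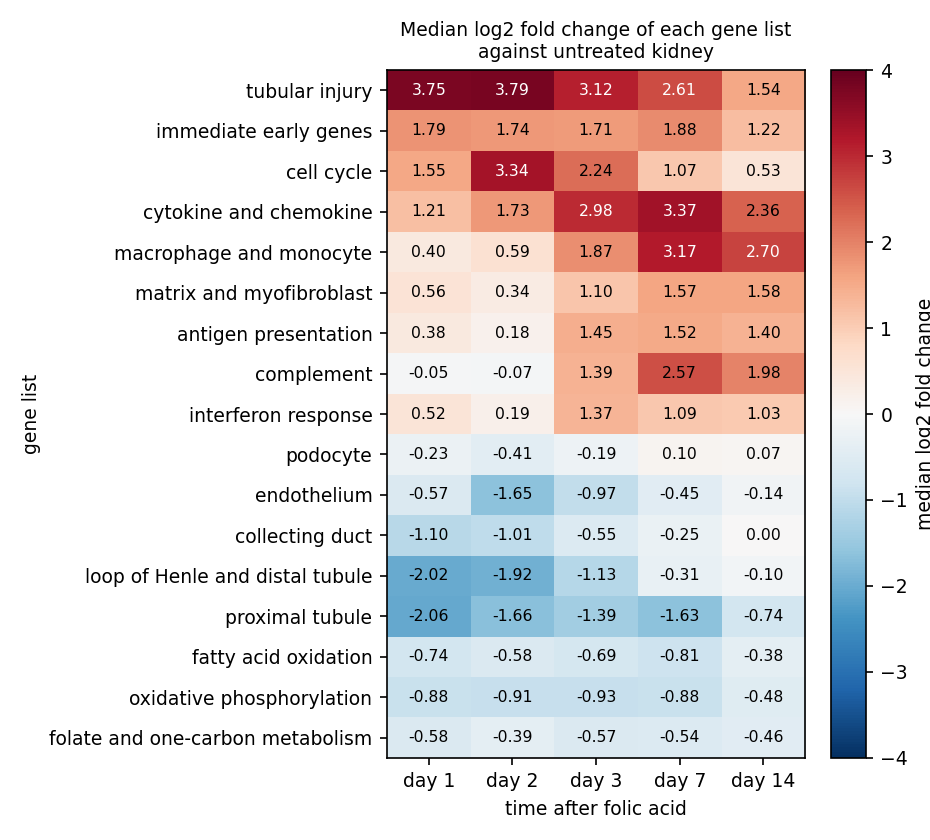
Median log2 fold change against untreated kidney (colour) of 17 gene lists at 5 days after folic acid, TMM scaling, 3 libraries per group. The tubular injury list was highest at day 1 and day 2 (3.75 and 3.79), and the matrix list was at 0.34 at day 2 and 1.58 at day 14. These medians turned positive with library totals alone: complement at days 1 and 2, collecting duct and folate at days 3 and 7, podocyte at day 3, and loop and distal and endothelium at days 7 and 14.

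**Figure D3:**
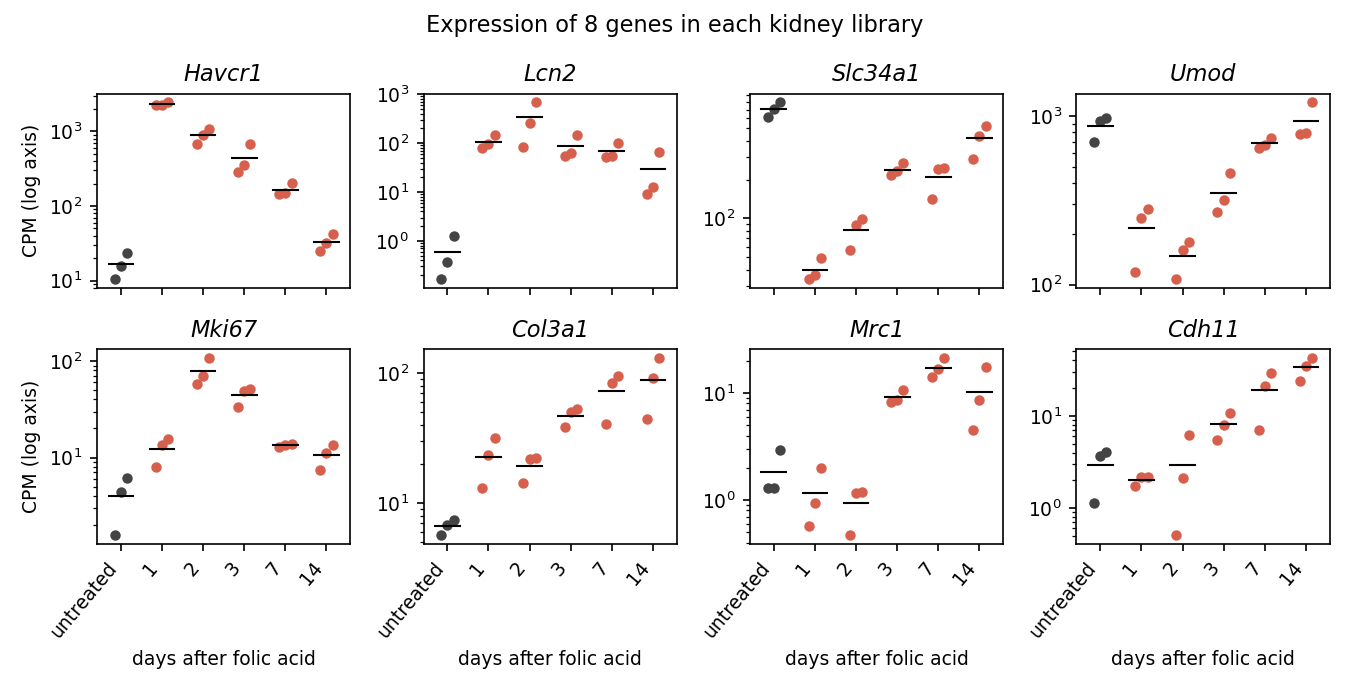
CPM of 8 genes on a log axis in untreated kidney and at 5 days after folic acid; points are the 3 libraries of a group and lines are group means. Havcr1 ran from 16.4 CPM untreated to 2338 at day 1 and 33.3 at day 14, and Cdh11 from 2.93 CPM untreated to 33.6 at day 14.

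Cdh11 and Mrc1, which the series title names, were chosen by the study on these samples, so their values here are not independent evidence. Cdh11 (ENSMUSG00000031673), a cadherin of mesenchymal cells, was at 2.93 ± 1.56 CPM in untreated kidney, 2.03 ± 0.257 at day 1, 2.93 ± 2.9 at day 2 and 8.06 ± 2.72 at day 3, and none of these days passed (adjusted p = 0.683, 0.945 and 0.16). It rose 6.59-fold to 19.1 ± 11.1 CPM at day 7 (log2 fold change 2.72, SE 0.64, adjusted p = 0.0138) and 11.6-fold to 33.6 ± 9.22 CPM at day 14 (log2 fold change 3.54, SE 0.66, adjusted p = 0.00874). The day 7 call was lost without untreated replicate 2 (log2 fold change 2.32, adjusted p = 0.0727) or day 7 replicate 1 (2.29, adjusted p = 0.07), and the day 14 call without untreated replicate 2 (3.13, adjusted p = 0.0585). Mrc1 (ENSMUSG00000026712), the mannose receptor of macrophages, was at 1.84 ± 0.952 CPM in untreated kidney and rose 5.02-fold at day 3 (adjusted p = 0.0142), 9.46-fold to 17.3 ± 3.59 CPM at day 7 (adjusted p = 0.00174) and 5.6-fold at day 14 (adjusted p = 0.0266). The day 3 call was lost without untreated replicate 1 (2.12, adjusted p = 0.0735) or 2 (2.10, adjusted p = 0.0747). The day 14 call was lost without untreated replicate 1 (2.29, adjusted p = 0.127) or 2 (2.26, adjusted p = 0.139) or day 14 replicate 3 (1.84, adjusted p = 0.171). Pltp, a phospholipid transfer protein gene, fell 14.9-fold from 0.635 ± 0.399 to 0.0349 ± 0.0311 CPM at day 1, a call lost without untreated replicate 2 (-3.22, adjusted p = 0.0614). At day 2 it was lower with 1 read against 60 (log2 fold change -5.05, adjusted p = 0.00906), a call lost without day 2 replicate 1 (-3.91, adjusted p = 0.0629). It was at 0.845 ± 0.21 CPM at day 3 (adjusted p = 0.837), 3.26 ± 2.19 at day 7 (adjusted p = 0.0801) and 2.08 ± 0.854 CPM at day 14 (adjusted p = 0.301). Among other fibrosis genes, Acta2, which encodes smooth muscle actin, was at 2.73 ± 0.825 CPM untreated and rose 8.91-fold to 24.7 ± 26.8 CPM at day 2 (adjusted p = 0.0133). That call was lost without untreated replicate 2 (log2 fold change 3.11, adjusted p = 0.0552) or 3 (2.94, adjusted p = 0.0636) or day 2 replicate 2 (1.77, adjusted p = 0.129). Acta2 was at 9.76 ± 9.77, 6.14 ± 2.27, 7.13 ± 3.17 and 5.42 ± 2.85 CPM at days 1, 3, 7 and 14, and none of these passed (adjusted p = 0.141, 0.395, 0.303 and 0.58). Tgfb1, a growth factor that drives fibrosis, was at 0.698 ± 0.155 CPM untreated and 2.1 ± 0.421 at day 7 (adjusted p = 0.173).

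Between consecutive times few genes passed. From day 1 to day 2 the edgeR test called 10 genes, 7 higher and 3 lower, with 2252 at an unadjusted p under 0.05. Division genes led the rises: Mki67 rose 6.4-fold from 12.2 ± 3.89 to 78.3 ± 25.7 CPM (log2 fold change 2.68, SE 0.41, adjusted p = 0.0191) and Foxm1 11.7-fold. The spindle gene Ska3 rose 19.5-fold, and the proximal lactate transporter gene Slc5a12 rose 5.32-fold. Dnase1 fell 10.8-fold from 72.4 ± 23.4 to 6.61 ± 3.81 CPM and Pzp, a protease inhibitor gene, fell 9.72-fold. Of 49 cell cycle genes 3 rose (23 adjusted over the list alone, median log2 fold change 1.51, adjusted p = 9.95e-23, and adjusted p = 0.000304 with an estimated correlation). Of 24 endothelial genes 0 passed by edgeR (7 lower and 1 higher adjusted over the list alone), with 10 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom (median log2 fold change -1.13, adjusted p = 1.86e-05, and adjusted p = 0.0127 with an estimated correlation). The count of genes was 1 without day 1 replicate 1, 6 without day 1 replicate 2 (all lower), 158 without day 2 replicate 1, 1 without day 2 replicate 2 and 130 without day 2 replicate 3. None of the 8 named genes passed in every such fit. Without day 2 replicate 2, Mki67 had a log2 fold change of 2.38 (adjusted p = 0.0572), Foxm1 3.54 (adjusted p = 0.0738), Slc5a12 2.11 (adjusted p = 0.0804), Dnase1 -3.27 (adjusted p = 0.0512) and Pzp -3.25 (adjusted p = 0.0572). Without day 1 replicate 1, 2 or 3, Mki67 had adjusted p = 0.0726, 0.0938 and 0.0616, Foxm1 had 0.128, 0.152 and 0.126, Ska3 had 0.0726, 0.0938 and 0.0788, and Slc5a12 had 0.0819, 0.138 and 0.0788. Pzp had adjusted p = 0.069 without day 1 replicate 1. Foxm1 was at 2.81 on the log2 scale without day 2 replicate 1, against 3.55, and Dnase1 at -4.05 without day 2 replicate 3, against -3.43.

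From day 2 to day 3, 37 genes rose and 5 fell, with 2600 at an unadjusted p under 0.05. Egf rose 11.8-fold from 1.91 ± 0.991 to 24.3 ± 14.3 CPM (log2 fold change 3.56, SE 0.47, adjusted p = 0.00304), Cyp2e1 4.71-fold and Miox, the inositol-breaking oxygenase of the proximal tubule, 4.42-fold to 70 ± 12.8 CPM. The macrophage receptor gene Adgre1, also known as F4/80, rose 14.1-fold from 0.229 ± 0.214 to 4.0 ± 1.51 CPM, the class II gene H2-Aa 5.31-fold to 61.1 ± 24.8 CPM and C1s1 11.6-fold. These 6 genes passed in each fit that left out 1 library. Of 22 antigen presentation genes 2 rose (10 adjusted over the list alone, median log2 fold change 1.14, adjusted p = 7.96e-08, and adjusted p = 0.0285 with an estimated correlation). Of 25 complement genes 3 rose (4 adjusted over the list alone, median log2 fold change 0.97, adjusted p = 3.36e-06, and adjusted p = 0.0285 with an estimated correlation), of 34 macrophage genes 1 rose (7 adjusted over the list alone, median log2 fold change 1.21, adjusted p = 4.08e-07, and adjusted p = 0.0541 with an estimated correlation), and of 53 matrix genes 2 rose (18 rose and 2 fell adjusted over the list alone, median log2 fold change 0.80, adjusted p = 1.16e-06, and adjusted p = 0.0856 with an estimated correlation). Of 54 proximal tubule genes 4 rose (15 rose and 2 fell adjusted over the list alone, median log2 fold change 0.25, adjusted p = 6.07e-05, and adjusted p = 0.306 with an estimated correlation). In the cell cycle list 0 of 49 genes passed by edgeR (4 lower adjusted over the list alone), with 14 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom (median log2 fold change -0.81, adjusted p = 8.74e-08, and adjusted p = 0.0285 with an estimated correlation). Egf was at 2.96 on the log2 scale without day 3 replicate 3. The count was 272 without day 2 replicate 1 (74 higher and 198 lower), 14 without day 2 replicate 2 (all higher) and 216 without day 2 replicate 3 (63 higher and 153 lower), so the excess of rises rests on the libraries used. Without a low-count filter 196 genes were higher and 192 lower, and by DESeq2 367 and 347.

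From day 3 to day 7 the edgeR test called 3 genes, all higher, with 1698 at an unadjusted p under 0.05. Sema3d, a secreted guidance protein gene, rose 21.8-fold from 0.569 ± 0.296 to 12.4 ± 4.22 CPM (log2 fold change 4.45, SE 0.67, adjusted p = 0.0323) and Nid1, a basement membrane protein gene, rose 3.41-fold from 30 ± 5.96 to 102 ± 36.5 CPM (log2 fold change 1.77, SE 0.27, adjusted p = 0.0323). Without day 3 replicate 1, 2 or 3 or day 7 replicate 1 or 3 the count was 0, with adjusted p = 0.107, 0.0997, 0.0881, 0.0789 and 0.1 for Sema3d and 0.107, 0.0997, 0.0881, 0.0789 and 0.14 for Nid1. DESeq2 called 218 genes and limma-voom 11. In the loop and distal list 0 of 23 genes passed by edgeR (8 higher adjusted over the list alone), with 12 at an unadjusted p under 0.05, 4 by DESeq2 and 2 by limma-voom (median log2 fold change 0.90, adjusted p = 1.78e-09, and adjusted p = 0.0237 with an estimated correlation). In the cell cycle list 0 of 49 passed by edgeR (12 lower adjusted over the list alone), with 17 at an unadjusted p under 0.05, 9 by DESeq2 and 0 by limma-voom (median log2 fold change -1.15, adjusted p = 3.57e-12, and adjusted p = 0.00564 with an estimated correlation).

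From day 7 to day 14 the test called 3 genes, with 1588 at an unadjusted p under 0.05. Havcr1 fell 4.98-fold from 166 ± 34.1 to 33.3 ± 8.8 CPM (log2 fold change -2.32, SE 0.33, adjusted p = 0.0215) and Plscr1, a lipid scramblase gene induced by interferon, fell 3.71-fold, while Dnase1 rose 6.32-fold to 207 ± 89.8 CPM. Of 27 tubular injury genes 1 fell (6 adjusted over the list alone, median log2 fold change -0.79, adjusted p = 1.57e-11, and adjusted p = 0.0953 with an estimated correlation). In the proximal tubule list 0 of 54 genes passed by edgeR (29 higher and 1 lower adjusted over the list alone), with 32 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom (median log2 fold change 0.97, adjusted p = 2.19e-18, and adjusted p = 0.0953 with an estimated correlation). The count was 5 without day 7 replicate 2, 1 without day 7 replicate 3, 0 without day 14 replicate 1 or 2 and 56 without day 14 replicate 3 (46 higher and 10 lower). Without day 7 replicate 3 and day 14 replicate 1 and 2, Havcr1 had adjusted p = 0.0894, 0.0646 and 0.172, Plscr1 had 0.191, 0.0646 and 0.172, and Dnase1 had 0.191, 0.0752 and 0.172. Without day 7 replicate 1, Plscr1 had adjusted p = 0.0811 and Dnase1 had 0.26. Without day 14 replicate 3, 12 proximal tubule genes rose (median 1.19, adjusted p = 0.00659 with an estimated correlation) and 3 tubular injury genes fell (median -1.07, adjusted p = 0.0214 with an estimated correlation).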

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

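The tests of the mitochondrial share, of the difference between proximal and distal tubule, and of other splits of the samples were chosen after the result was seen, as was the margin used for the missing genes of day 2 replicate 2; the other tests were written before.

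Counts between consecutive times are tests of whether the effects at both times differ, since the untreated libraries cancel. They gave 10 genes for day 2 against day 1, 42 for day 3 against day 2, 3 for day 7 against day 3 and 3 for day 14 against day 7. With 3 libraries against 3 there are 10 splits, so a share under 0.05 cannot be reached, with 1 of 10 splits, the real one, as large in each comparison but the last. The highest count in another split was 1 for day 2 against day 1, 0 for day 3 against day 2 and 0 for day 7 against day 3. For day 14 against day 7 another split gave 4 genes against the real 3, so 2 of the 10 splits were as large. Against untreated kidney the real counts were 1792, 2216, 1280, 1298 and 260, and the edgeR count in each other split was 0 at all 5 days. Across the 6 groups none of 99 random groupings reached 3315 genes (highest 89). This argues against chance at 1 of 100, the lowest share reachable.

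Reads in no annotated gene, which no comparison used, took 21.46% of all reads at day 3, 22.72% at day 7 and 19.3% at day 14, against 15.7 ± 1.65% in untreated kidney. A fall of the mitochondrial share is argued against as the whole cause, since with mitochondrial genes left out of the total the share was 55.1 ± 0.39% at day 7 and 47.9 ± 1.52% untreated, 7.15 points apart. Read depth is argued against too: its slope within groups predicted -0.158 of the 7.07 points. Unspliced RNA, genomic DNA and transcripts missing from the annotation were not tested and stay open, as does a biological change after folic acid. Reads with more than 1 alignment took 25.87% at day 2 and 27.07% at day 3, against 21.7 ± 2.00% untreated.

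Day 2 replicate 2 stood apart, with the fewest reads (8.68 M, or 1e6 reads) and a score of 129.9 on the first principal component against 52.5 and 54.7 in the other day 2 libraries. Low depth alone is argued against: with every library thinned to 2.826 M reads outside the mitochondrial genome, it had 118 genes over 10 times both other libraries of its group, against at most 64 in the other 17. As deposited, Sirt7 was at 3010 CPM there and at 18.9 and 20.2 in the others, and Atf7ip at 2860 against 65.6 and 83.8. Few molecules entering the library may be a candidate cause: after thinning it lacked 2 genes that both others held, against at most 1 elsewhere. By the bound written before this counts for that cause, but a margin of 1 gene was then judged too small to decide, so it stays open.

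At day 7 the proximal tubule list was low while the loop and distal list was near its untreated level. Within a library the proximal minus distal median log2 CPM was 2.76 ± 0.42 in untreated kidney and 1.43 ± 0.36 at day 7, a difference of -1.33. Dilution of all tubule cells by other cells, such as entering leukocytes, moves both lists alike and is argued against as the whole cause by that value. A scaling factor common to a library cancels from it by construction. Fewer proximal cells or less transcript per cell are hypotheses that bulk RNA cannot tell apart.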

How the results depend on the processing

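The fits without day 2 replicate 2 across all comparisons and without mitochondrial genes, and the lists without day 14 replicate 3, were chosen after the data were seen; all other alternatives were set before. For the 528 gene results, 7737 alternatives kept direction and call, 1043 kept the direction and lost the call, 7 gained one and 6 reversed, and 29 gave no adjusted p. For lists 860 kept both, 95 lost the call, 19 gained one and 14 reversed. The cause was not tested for the results that moved.

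With library totals alone the counts were 2238 at day 3, 2565 at day 7 and 435 at day 14 against untreated, 166 for day 3 against day 2 and 0 for day 7 against day 3 by edgeR (1529 at an unadjusted p under 0.05; TMM gave 3, DESeq2 218 and limma-voom 11). Umod at day 7 reversed to 0.343. The direction of these lists against all other genes turned, whatever the sign of their median, with medians of 0.471 for NRF2 targets at day 3, 0.382 for the unfolded protein response at day 14, 0.284 for red blood cell at day 2 against day 1, 0.416, 0.384 and 0.42 for fatty acid oxidation, oxidative phosphorylation and the unfolded protein response at day 3 against day 2, and -0.27 for NRF2 targets at day 14 against day 7.

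Without a low-count filter 480 genes passed at day 14, and 248, 388, 48 and 32 between consecutive times in order; with a filter of 1 CPM in 3 samples 18 passed for day 2 against day 1. DESeq2 called 2144 genes at day 3, 2131 at day 7, 926 at day 14, 500, 714, 218 and 155 between consecutive times and 5284 across the 6 groups. In simulated counts with fewer changed genes, 36 of 149 DESeq2 and 4 of 86 edgeR calls at day 2 were false. Whether DESeq2's calls here are false was not tested. Limma-voom called 760 higher and 875 lower genes at day 2, 502 and 690 at day 3 and 498 and 705 at day 7, with more falls than rises unlike edgeR, 12 genes for day 3 against day 2, 11 for day 7 against day 3 and 2101 across the groups. With a replicate block 2 genes passed for day 2 against day 1 and 1 for day 14 against day 7. Red blood cell genes for day 2 against day 1 likewise turned direction (median 0.151).

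With only the compared groups fitted, 1847 genes passed at day 1, 1186 at day 2 and 71 at day 14. Between consecutive times such edgeR fits gave 0 genes each, with 1422, 1574, 1590 and 1323 at an unadjusted p under 0.05. Their dispersion came from only 6 libraries. Without day 2 replicate 2, 1992 genes passed at day 1, 1572 at day 2 and 6 for day 7 against day 3. The lists whose direction against all other genes turned had medians of -0.042 for tubular injury and 0.014 for neutrophil at day 2 against day 1. At day 3 against day 2 such medians were 0.508 for neutrophil, 0.055 for fatty acid oxidation, 0.211 for cholesterol synthesis and 0.571 for adrenal and adipose tissue. Of 234 list tests, 143 passed with the preset correlation and 71 with an estimated one. Cdh11, Mrc1 and Pltp had 7 calls against untreated, and 7 to 9 with other scaling, filter, tool or block.

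Leaving out 1 library at a time gave 1164 to 1379 genes at day 1, 1453 to 2005 at day 2, 614 to 1046 at day 3, 607 to 1014 at day 7 and 106 to 351 at day 14. Between consecutive times the ranges were 1 to 158, 14 to 272, 0 to 2 and 0 to 56. Across these fits Cdh11 at day 2 ran from -0.931 to 0.506, Slc19a1 at day 2 from -0.161 to 2.457 and Umod at day 14 from -0.145 to 0.195. Slc19a1 was called at day 2 (1.98, adjusted p = 0.048) and was at -0.161 without day 2 replicate 2, and its call was also lost without untreated replicate 1, 2 or 3 (adjusted p = 0.105, 0.141 and 0.146).

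Depth and replicate number limit small changes (median SE 0.55 log2). In simulated counts at day 2 depth edgeR recovered 2, 16, 28 and 36 (DESeq2 4, 29, 39 and 41) of 50 genes changed by 2-, 4-, 8- and 16-fold. So a gene that did not pass may have changed.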

Other observations

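All tests of lists below were set before the data were examined, apart from that without day 14 replicate 3. Of 27 p53 target genes 7 rose at day 1 (11 rose and 1 fell adjusted over the list alone, median log2 fold change 0.56, adjusted p = 0.000589, and adjusted p = 0.0098 with an estimated correlation), 7 at day 2, 5 at day 3, 4 at day 7 (median log2 fold change 0.52, adjusted p = 0.0167, and adjusted p = 0.028 with an estimated correlation) and 1 at day 14 (adjusted p = 0.324, and adjusted p = 0.332 with an estimated correlation). Gdf15, a cytokine of cell stress, rose 9.62-fold at day 1 and 19.5-fold at day 2, from 0.603 ± 0.241 CPM. Of 32 NRF2 target genes 10 rose and 1 fell at day 1 (14 and 1 adjusted over the list alone, median log2 fold change 0.76, adjusted p = 6.64e-06, and adjusted p = 0.0185 with an estimated correlation). Hmox1, the heme oxygenase of oxidative stress, rose 7.22-fold from 6.78 ± 2.38 to 48.9 ± 12.7 CPM and the reductase gene Akr1b8 rose 84.7-fold. At day 7 5 NRF2 targets fell and 1 rose (6 and 2 adjusted over the list alone, median log2 fold change -0.27, adjusted p = 0.0205, and adjusted p = 0.159 with an estimated correlation), with Fth1, the ferritin heavy chain, down 2.9-fold, and with library totals alone the median was 0.400. Of 24 cholesterol synthesis genes 4 fell at day 2 (4 fell and 1 rose adjusted over the list alone, median log2 fold change -0.62, adjusted p = 0.00338, and adjusted p = 0.0196 with an estimated correlation), with the sterol demethylase gene Cyp51 down 14.7-fold from 65.2 ± 5.16 to 4.49 ± 1.36 CPM. In this list 4 genes also fell at day 3, 4 at day 7 and 1 at day 14 (medians -0.43, -0.39 and -0.24, adjusted p = 0.00987, 0.014 and 0.0276 with an estimated correlation, and with library totals alone medians of 0.128, 0.276 and 0.063), and at day 1 4 fell and 1 rose (median log2 fold change -0.36, adjusted p = 0.119, and adjusted p = 0.127 with an estimated correlation). Of 27 unfolded protein response genes 4 rose and 2 fell at day 1 (4 and 3 adjusted over the list alone, median log2 fold change 0.05, adjusted p = 0.315, and adjusted p = 0.445 with an estimated correlation). Asns, which makes asparagine, rose 18.1-fold and Xbp1, a transcription factor of this response, rose 3.01-fold, while Herpud1 fell 3.62-fold. These genes passed in each fit that left out 1 library, with Asns at 3.54 on the log2 scale without untreated replicate 2, against 4.18.

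Lymphocyte, neutrophil and blood genes had few reads. Of 13 T and natural killer cell genes 1 rose at day 3 (2 rose and 1 fell adjusted over the list alone, median log2 fold change 0.42, adjusted p = 0.234, and adjusted p = 0.304 with an estimated correlation), the chemokine gene Ccl5, at 24.5-fold from 0.172 ± 0.245 to 5.05 ± 3.0 CPM (log2 fold change 4.62, and 7.21 without untreated replicate 2). At day 7, 1 of these genes rose and 1 fell (median log2 fold change 1.53, adjusted p = 0.0457, and adjusted p = 0.11 with an estimated correlation). At day 14 the edgeR count was 0, with 4 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom (median log2 fold change 1.10, adjusted p = 0.0139, and adjusted p = 0.0644 with an estimated correlation). Of 9 B and plasma cell genes 2 fell at day 2, also adjusted over the list alone (median log2 fold change -0.54, adjusted p = 0.0308, and adjusted p = 0.145 with an estimated correlation), and Jchain, the joining chain of secreted antibody, had no read there and was at least 58.2-fold lower. Of 6 neutrophil genes 1 was higher at day 14, Lcn2, which is also in the tubular injury list (3 adjusted over the list alone, median log2 fold change 2.59, adjusted p = 0.000567, and adjusted p = 0.0413 with an estimated correlation, the latter 0.0532 without day 14 replicate 3). Of 10 red blood cell genes 4 fell and 1 rose at day 3 (6 and 1 adjusted over the list alone, median log2 fold change -1.90, adjusted p = 0.00957, and adjusted p = 0.112 with an estimated correlation). The hemoglobin genes Hba-a1 and Hba-a2, near-identical copies whose values are uncertain, had no read at day 3 and were at least 22.1-fold and at least 19-fold lower. In the 9 adrenal and adipose genes, a sign of tissue carried over at dissection, the edgeR count was 0 at day 7, with 2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom (median log2 fold change -2.60, adjusted p = 0.00435, and adjusted p = 0.18 with an estimated correlation).

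With genes that had no read in a group set at their bound, list medians came down: cytokine and chemokine from 1.73 to 0.95 at day 2, from 2.98 to 2.86 at day 3, from 3.37 to 2.37 at day 7 and from 2.36 to 2.25 at day 14, neutrophil from 2.83 to 1.14 at day 1, from 2.69 to 1.94 at day 2 and from 2.74 to 2.29 at day 7, and tubular injury from 3.12 to 2.88 at day 3.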
